A study of Mus musculus with 4 samples.

How the data were processed

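Gene expression was measured in mouse skeletal stem cells (SSCs) taken from 4 to 6 week old mice with intact Mmp14 (wild type) or without it (Mmp14 knockout) and kept in 3D collagen gel for 48 h. Per the labels' protocols, RNA was purified with a fibrous tissue kit, 10 ng of total RNA was amplified to cDNA with the Nugen Ovation PicoSL WTA system, and 3.75 µg of cDNA was labelled with biotin. The series design names Affymetrix microarrays. There were 4 arrays, 2 wild type and 2 knockout, numbered 1 and 2 within each group. The labels do not say whether the replicates came from separate animals or cultures, so p-values then measure only the spread between these samples, which may be technical.

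The deposited values were log2 intensities, 1 per probe set and array, for 41345 probe sets. The submitters' processing notes name limma and oligo, without version or role. The method of normalization was not stated in the sources used here. The scale was read from the values: the deposited log2 intensities ran from 0.43 to 12.2, with array medians of 2.32 and 2.36 in wild type and 2.37 and 2.36 in knockout. Scanner files and detection calls were not used here. The number of arrays limits the precision.

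Gene symbols were taken from the probe annotation supplied with the table. Of the probe sets, 23521 had exactly 1 gene symbol, 1814 had several and 16010 had no listed symbol. Entrez identifiers of 23328 of the 1-symbol probe sets were found in the RefSeq annotation of GRCm38.p6, and no symbol needed updating. That annotation was used for names, for autosomal or X-linked status and for which genes neighbour each other, and no coordinates are given because the build behind the array is not named. The probe set with the highest mean stood for a gene, which gave 22180 genes. Genes with a mean of at least 2.34 log2, the median row mean of the whole table, were tested, leaving 12708.

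Knockout and wild type were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided), without a block and with 2 residual degrees of freedom. The prior had 3.99 degrees of freedom and an SD of 0.12 log2. P-values were adjusted by Benjamini and Hochberg, and a gene was called when its adjusted p was below 0.05. All fold changes are knockout minus wild type on the log2 scale. The replicate numbers were not treated as pairs: the deviations of same-numbered arrays from their group means correlated at −0.04 across genes.

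The comparison, the gene lists and the rule for naming genes were set before the data were examined. Mmp14 was named first, then the 10 largest called changes in each direction whose groups did not overlap, leaving out unnamed loci, and then up to 4 measured members of each list, called members first. The lists covered the MMP and TIMP family, ADAM and ADAMTS proteases, YAP/TAZ targets, SRF/MRTF and contractile genes, osteoblast, adipocyte and chondrocyte lineages, skeletal stem and stromal markers, collagens and matrix, collagen processing enzymes, integrins with collagen receptors and adhesion genes, Notch and Wnt pathways, TGF-beta and BMP response, FGF/ERK response, mesenchymal transcription factors, cell cycle, p53 and senescence, inflammatory cytokines and NF-kB targets, interferon response, hypoxia and glycolysis, unfolded protein and integrated stress response, cholesterol and fatty acid synthesis, cytosolic ribosomal proteins, and Y-linked and X-inactivation genes. Markers of other cell types covered macrophages and leukocytes, granulocytes, lymphocytes, erythroid cells and megakaryocytes, osteoclasts, endothelium, pericytes and smooth muscle, skeletal muscle, and Schwann and neural cells. Mmp14 was in no list. Lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists tested.

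The fit was tested on simulated data in 20 simulations of the 12708 genes with 200 changed genes each. Of genes simulated with a knockout against wild type change of 0.5 log2, 3.4% were called, against 76% at 1 log2 and 97.8% at 2 log2. Of the calls, 5.4% were unchanged genes on average. With independent genes, 0.05 lists were called per simulation. The simulated noise was independent between genes, with variances drawn from the prior fitted to these data. The 200 changed genes were also fewer than the 1439 called in the data. These rates therefore check the procedure and need not hold for the real arrays.

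Alternatives covered no filter and a stricter filter on dim genes (mean of at least 4.76 log2, the 75th percentile), the replicate number as a block, quantile normalization of the arrays, centring on array medians, eBayes with trend and robust, array weights, the mean of a gene's probe sets, leaving out each array, other thresholds, every probe set of the table, camera with an estimated correlation, and fry. A fit of every probe set with trend and robust eBayes was added after seeing the data.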

Results

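The data were 4 arrays of skeletal stem cells kept in 3D collagen gel for 48 h, 2 from Mmp14 wild-type mice and 2 from Mmp14 knockout mice. Mmp14 encodes MT1-MMP, a membrane-anchored matrix metalloproteinase that cleaves collagen. The 12708 tested genes correlated at 0.992 between the wild-type arrays, at 0.994 between the knockout arrays and at 0.970 to 0.975 between the groups. The median absolute difference between replicates was 0.140 log2 in wild type and 0.116 in knockout.

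Mmp14 itself was measured at 8.77 and 8.83 log2 in the wild-type arrays and at 5.77 and 5.84 in the knockout arrays. It fell by 2.99 log2 (SE 0.103, n = 2 per group, limma adjusted p = 0.000278), which was 7.95-fold lower and left 12.6% of the wild-type level. Mmp14 had a single probe set, and the labels do not say which part of the gene was deleted, so the remaining signal does not measure intact transcript. Markers of sex also differed between the groups. Xist, which is expressed from the inactive X chromosome, rose from 8.47 to 9.19 log2 in knockout (limma adjusted p = 0.0155). The Y-linked gene Eif2s3y fell from 5.98 to 5.29 (limma adjusted p = 0.0474), while the Y-linked Kdm5d and Uty had values of −0.42 and −0.25 and were not called. The call of Eif2s3y was lost without a filter on dim genes (adjusted p = 0.0676), without wild type replicate 1 (0.107), without Mmp14 knockout replicate 1 (0.176) and without Mmp14 knockout replicate 2 (0.0648), and that of Xist without Mmp14 knockout replicate 1 (0.0801). All 4 arrays carried signal from both Xist and the Y-linked genes.

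The stated purpose of the comparison of knockout with wild-type cells was to screen for transcriptional changes. Feedback inhibitors of Wnt signalling were among the genes that fell most, including Nkd2 (21.9-fold lower) and Axin2 (13.8-fold lower, with −1.31 log2 at its second probe set), while the Wnt-enhancing secreted factors Rspo3 and Rspo2 rose by 3.19 and 2.29 log2, and the Wnt list as a whole was not called. The osteoblast transcription factor Sp7 fell, and the collagenase gene Mmp13 rose by 3.34 log2. The lists of FGF/ERK response genes (higher) and of cell cycle and cholesterol synthesis genes (lower) were called. Each of these 3 calls was lost at an adjusted p = 0.58 with an estimated correlation. Of the genes tested, 1439 (11.3%) were called, 788 higher and 651 lower in knockout. At least a 2-fold change was found in 272 of the higher and 174 of the lower genes.

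The groups did not overlap in any of the 1439 called genes, nor in 57.8% of all tested genes, against 33.3% by chance. The number of calls depended on the fit. With every probe set of the table in 1 fit, which also dropped the filter on dim genes and the choice of 1 probe set per gene, 129 were higher and 89 lower, and 187 of the 1439 genes remained called. Every group of genes given here was measured in the same 4 arrays as the shifts of Xist (0.73) and Eif2s3y (−0.69).

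The 10 largest increases were in Cytl1, Stk32b, Rassf4, Slc14a1, Mmp13, Col14a1, Rspo3, Hpse2, Otor and Angptl7, from 4.11 log2 for Cytl1 (SE 0.207, limma adjusted p = 0.000917, n = 2 per group) down to 3.02 for Angptl7. Cytl1, a secreted cytokine-like protein, went from 4.86 ± 0.38 to 8.96 ± 0.23 log2 (SD, n = 2). Slc14a1 encodes a urea transporter, Col14a1 a fibril-associated collagen and Hpse2 a relative of heparanase. Leaving out unnamed loci, the 10 largest decreases were in Tnfrsf19, Nkd2, Axin2, Sp7, Tnn, Bmp3, Mmp14, Arsi, Ahr and Gem. The unnamed locus C430002N11Rik fell by 3.88 log2, more than Axin2. Tnfrsf19, a TNF receptor family member, fell by 4.79 log2 (SE 0.122, limma adjusted p = 0.000153, n = 2 per group), from 7.85 ± 0.14 to 3.07 ± 0.10 log2 (SD, n = 2). Tnn encodes tenascin-W, Bmp3 a bone morphogenetic protein family member, Ahr the aryl hydrocarbon receptor and Gem a small GTPase.

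**Figure D1:**
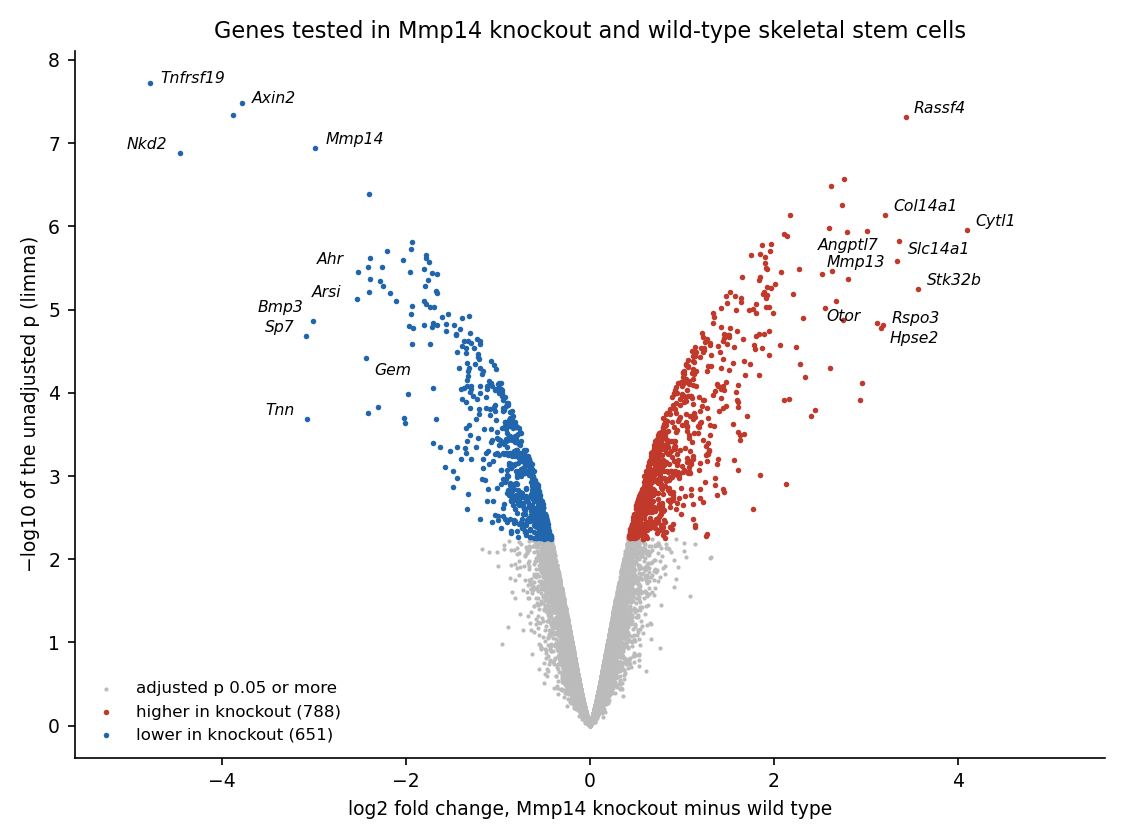
Each point is 1 of the 12708 tested genes, with the log2 fold change of knockout against wild type on the x axis and −log10 of the unadjusted limma p on the y axis. The 788 genes called higher are red and the 651 called lower are blue. The 10 largest changes in each direction, unnamed loci left out, are named, from −4.79 for Tnfrsf19 to 4.11 for Cytl1.

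Wnt pathway genes moved apart. Of 23 tested members, 7 rose, 11 fell and 5 were not called, or 8 and 11 adjusted over the list alone. The genes that fell included the feedback inhibitors Nkd2 (−4.45), Axin2 (−3.78), Dkk2 (−2.41) and Notum (−2.40), and the transcription factor Lef1 (−1.66). A second probe set gave −1.31 for Axin2 and −0.30 for Notum. Rspo3, Rspo2, the secreted inhibitor Frzb (1.96) and Wnt5a (1.79) rose. The list's median was −0.30, and the list was not called (camera adjusted p = 0.118), although it was without the filter on dim genes (adjusted p = 0.026).

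FGF/ERK response genes rose as a list (median 0.87, camera adjusted p = 8.93e-07), but the call was lost at an adjusted p = 0.58 with an estimated correlation. Of 23 members, 13 rose, 2 fell and 8 were not called, or 14 and 2 adjusted over the list alone. Etv1 (2.80) and Etv5 (1.45), transcription factors induced by FGF, rose with the ERK phosphatase gene Dusp6 (2.17) and the feedback inhibitor Spry1 (2.08). A second probe set gave 0.73 for Etv1 and 0.12 for Etv5. Ier3 (−1.41) and the receptor Fgfr2 (−0.94) fell.

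The list of TGF-beta and BMP response genes fell (median −0.23, camera adjusted p = 0.0137), with an adjusted p = 0.58 with an estimated correlation. It also held genes of ligands, receptors and antagonists, such as Bmp4, Tgfbr1 and Nog, so its fall does not measure the response alone. Of 26 members, 2 rose, 8 fell and 16 were not called, or 3 and 11 adjusted over the list alone. Inhba (−1.79), which encodes an activin subunit, Bmper (−1.67), Pmepa1 (−1.30) and Atoh8 (−1.29) fell most, and Id4 rose (0.89). The list was not called without wild type replicate 2 (adjusted p = 0.0588).

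Of 10 tested Notch pathway members, 2 rose, 2 fell and 6 were not called, or 3 and 2 adjusted over the list alone, with Hey2 at −2.25. The other 3 calls were lost on leaving out single arrays: Notch1 without wild type replicate 1 (adjusted p = 0.082) or Mmp14 knockout replicate 1 (0.133), Dtx4 without wild type replicate 2 (0.0606) or Mmp14 knockout replicate 2 (0.0702), and Hes1 without any of wild type replicate 2 (0.132), Mmp14 knockout replicate 1 (0.136) or 2 (0.176). The list was not called (camera adjusted p = 0.991), and its median (−0.0036) and mean (−0.09) were below 0 while the test pointed up.

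Of 12 tested members of the osteoblast list, 1 rose, 6 fell and 5 were not called, or 3 and 6 adjusted over the list alone. Sp7, the transcription factor required for bone formation, fell by 3.08 log2 (SE 0.257), with Alpl (−1.76), Msx2 (−1.70) and Dlx5 (−1.04). Alpl encodes alkaline phosphatase, and its second probe set gave −1.06. Dmp1, a matrix protein gene of osteocytes, rose to 5.08 log2 from a wild-type signal of 2.12, which was below the 2.34 set for dim genes, so its fold is not given. The list had a median of −0.43 and was not called (camera adjusted p = 0.145), although it was under the stricter filter (median −1.37, camera adjusted p = 0.000646). That filter left out dim members, among them Dmp1, the only one that rose, and Smpd3, which fell, so the 2 results cover different members.

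Adipocyte genes included 6 that rose, 2 that fell and 13 not called of 21, or 6 and 5 adjusted over the list alone. Pparg, the master regulator of fat cell formation, rose by 2.31, with Angptl4 (2.76), Klf15 (1.91) and Plin4 (1.36). The wild-type signal of Klf15 (2.35 log2) lay just above the 2.34 set for dim genes, so the size of its rise is uncertain. The genes that fell were Scd1 (−1.23) and Fasn (−0.46). The mature fat cell genes Adipoq (−0.11) and Fabp4 (−0.07) were not called. Both were dim, with wild-type and knockout means of 2.43 and 2.32 log2 for Adipoq and 2.86 and 2.79 for Fabp4. Signal that close to the array medians says little about whether these 2 genes changed. The median was 0.02 and the list was not called (camera adjusted p = 0.36).

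Chondrocyte genes moved apart: 4 rose, 3 fell and 15 were not called of 22, or 7 and 4 adjusted over the list alone. Ucma, Cnmd (1.56) and the transcription factor Sox9 (1.92) rose, while the proteoglycan gene Acan fell by 1.97. Col2a1, the main cartilage collagen gene, had a value of −0.08 and was not called. The median was 0.07 and the list was not called (camera adjusted p = 0.344).

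Skeletal stem and stromal markers rose as a list (median 0.23, camera adjusted p = 0.0153), with an adjusted p = 0.58 with an estimated correlation. Of 22 members, 8 rose, 1 fell and 13 were not called, or 10 and 3 adjusted over the list alone. The chemokine gene Cxcl12 (1.81), the receptor gene Pdgfra (1.77) and Postn (1.64) rose, and the leptin receptor gene Lepr, a marker of marrow stromal cells, fell by 2.26. The list was not called without wild type replicate 1 (adjusted p = 0.0949).

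In the MMP and TIMP family, 3 of 15 tested members rose, 4 fell and 8 were not called, with the same counts adjusted over the list alone. Mmp13 rose by 3.34 (SE 0.195, limma adjusted p = 0.000993, n = 2 per group), and Mmp9 (0.76) also rose. Mmp3 rose to 3.35 log2 from a wild-type signal of 2.05, below the 2.34 set for dim genes. Mmp11 fell (−0.69), with −0.32 at its second probe set. Mmp9 was not called without wild type replicate 1 (adjusted p = 0.0624) or without Mmp14 knockout replicate 2 (0.0706), and Mmp11 without Mmp14 knockout replicate 1 (0.0801). Mmp2, whose protein is activated by MT1-MMP, had a value of 0.27 and was not called. The list's median was −0.05 while its mean (0.21) and test were up, and it was not called (camera adjusted p = 0.919).

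The list of ADAM and ADAMTS proteases, which also held the ADAMTS-like genes Adamtsl1 to Adamtsl4, rose (median 0.34, camera adjusted p = 0.0473). With an estimated correlation its camera adjusted p was 0.58. Of 22 members, 7 rose, 3 fell and 12 were not called, or 9 and 4 adjusted over the list alone. Adamts6 (1.97), Adamts1 (1.84) and the aggrecanase gene Adamts5 (1.10) rose, and Adamtsl1 fell (−1.33). The list was not called without wild type replicate 1 (adjusted p = 0.116), wild type replicate 2 (0.0588) or Mmp14 knockout replicate 1 (0.121).

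Among collagens and matrix genes, 6 of 35 rose, 3 fell and 26 were not called, or 8 and 8 adjusted over the list alone. Col14a1 (3.21) and the basement membrane collagen genes Col4a1 (1.03) and Col4a2 (1.06) rose, and elastin (Eln) fell by 1.58, without a call when wild type replicate 2 was left out (adjusted p = 0.06). Col1a1, the main collagen gene of bone, had a value of −0.16 and was not called. The list's median and test were down and its mean was 0.12 (camera adjusted p = 0.967). Of 21 collagen processing enzymes, 2 rose and 2 fell, with the same counts adjusted over the list alone, and 17 were not called. The prolyl hydroxylase gene P4ha2 fell by 1.70 (list camera adjusted p = 0.344). Without Mmp14 knockout replicate 2 the other 3 calls were lost, those of Pcolce2 (adjusted p = 0.132), Loxl3 (0.0845) and Lox (0.107), and Lox lost its call on leaving out any 1 array (0.0943 to 0.236). Loxl3 was also not called without wild type replicate 1 (0.072) or Mmp14 knockout replicate 1 (0.119), nor Pcolce2 without wild type replicate 2 (0.123).

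Of 24 integrins, collagen receptors and adhesion genes, 4 rose, 3 fell and 17 were not called, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.344). The integrin genes Itga8 (1.40), Itgb3 (1.34), Itga6 (1.28) and Itga2 (1.23) rose, and Itga11 fell (−0.65). The call of Itga6 was lost without a filter on dim genes (adjusted p = 0.0609), without Mmp14 knockout replicate 1 (0.0866) and without Mmp14 knockout replicate 2 (0.0905). Of 22 YAP/TAZ targets, 5 rose, 3 fell and 14 were not called, or 8 and 5 adjusted over the list alone (median 0.16, camera adjusted p = 0.239). Nuak2 (1.25) and Nt5e (1.10) rose, Tgfb2 (−1.80) and Ccn2 (−0.64) fell, and Ccn1 (−0.33) was not called. Fjx1 fell, but not without wild type replicate 2 (adjusted p = 0.0701). Of 24 SRF/MRTF and contractile genes, 1 rose, 2 fell and 21 were not called, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.896), with Fhl2 at 1.13 and Cnn1 at −0.73, and Cnn1 was not called without Mmp14 knockout replicate 2 (adjusted p = 0.0579). Fhl1, the other gene that fell, was not called without Mmp14 knockout replicate 2 (0.131), Mmp14 knockout replicate 1 (0.127) or wild type replicate 2 (0.105), nor without a filter on dim genes (0.0574). Of 15 tested members of the list of mesenchymal transcription factors, which also held the cadherin gene Cdh2 and the vimentin gene Vim, 2 rose, 3 fell and 10 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.344). Zeb1 (−1.04) and Twist1 (−1.02) fell, and Snai2 (0.74) and Cdh2 (0.75) rose, Cdh2 without a call when Mmp14 knockout replicate 1 was left out (adjusted p = 0.0548).

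Cell cycle genes fell as a list (median −0.71, camera adjusted p = 1.83e-12), with an adjusted p = 0.58 with an estimated correlation. Of 30 members, 17 fell, 13 were not called and 0 rose, or 24 fell adjusted over the list alone. Aurka (−1.21) and Plk1 (−1.12), kinases of mitosis, fell with cyclin A2 (Ccna2, −1.08) and the nucleotide synthesis gene Rrm2 (−1.03). Plk1 was not called without wild type replicate 1 (adjusted p = 0.0696) or without Mmp14 knockout replicate 1 (0.0711). Cholesterol and fatty acid synthesis genes also fell as a list (median −0.70, camera adjusted p = 1.05e-11), with an adjusted p = 0.58 with an estimated correlation. Of 22 members, 16 fell, 6 were not called and 0 rose, or 20 fell adjusted over the list alone, among them Cyp51 (−1.29), Fads2 (−1.01) and Mvk (−0.99). Unfolded protein and integrated stress response genes fell as a list (median −0.20, camera adjusted p = 0.0153), with an adjusted p = 0.58 with an estimated correlation. Of these 20 genes 2 fell and 18 were not called, or 1 rose and 6 fell adjusted over the list alone, with Vldlr at −1.44. That list was not called under the stricter filter (adjusted p = 0.0536), and Edem1, the other gene that fell, lost its call on leaving out any 1 array (0.0685 to 0.151).

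Of 18 p53 and senescence genes, 1 fell (Cdkn2b, −1.34) and 17 were not called, with the same count adjusted over the list alone (camera adjusted p = 0.344). Of 22 hypoxia and glycolysis genes, 2 rose (Adm 1.90, Car12 1.10) and 20 were not called, with the same count adjusted over the list alone (camera adjusted p = 0.344). The median of these 22 genes (−0.09) and the test were below 0 while the mean was 0.0062. Car12 was not called without wild type replicate 2 (adjusted p = 0.0599) or without Mmp14 knockout replicate 2 (0.0597). Of 13 inflammatory genes, 1 rose (Csf1, 0.56) and 12 were not called, with the same count adjusted over the list alone (camera adjusted p = 0.896), and the median was −0.01 while the mean (0.02) and the test were up. Csf1 lost its call on leaving out any 1 array (adjusted p = 0.0621 to 0.148). Of 13 interferon response genes, 1 rose, 1 fell and 11 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.752). Ifit3, which fell, was not called without wild type replicate 1 (adjusted p = 0.0829), wild type replicate 2 (0.111) or Mmp14 knockout replicate 2 (0.0544). With limma, 0 of 29 cytosolic ribosomal protein genes were called over all genes or adjusted over the list alone, and 1 had an unadjusted p below 0.05 (camera adjusted p = 0.344).

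**Figure D2:**
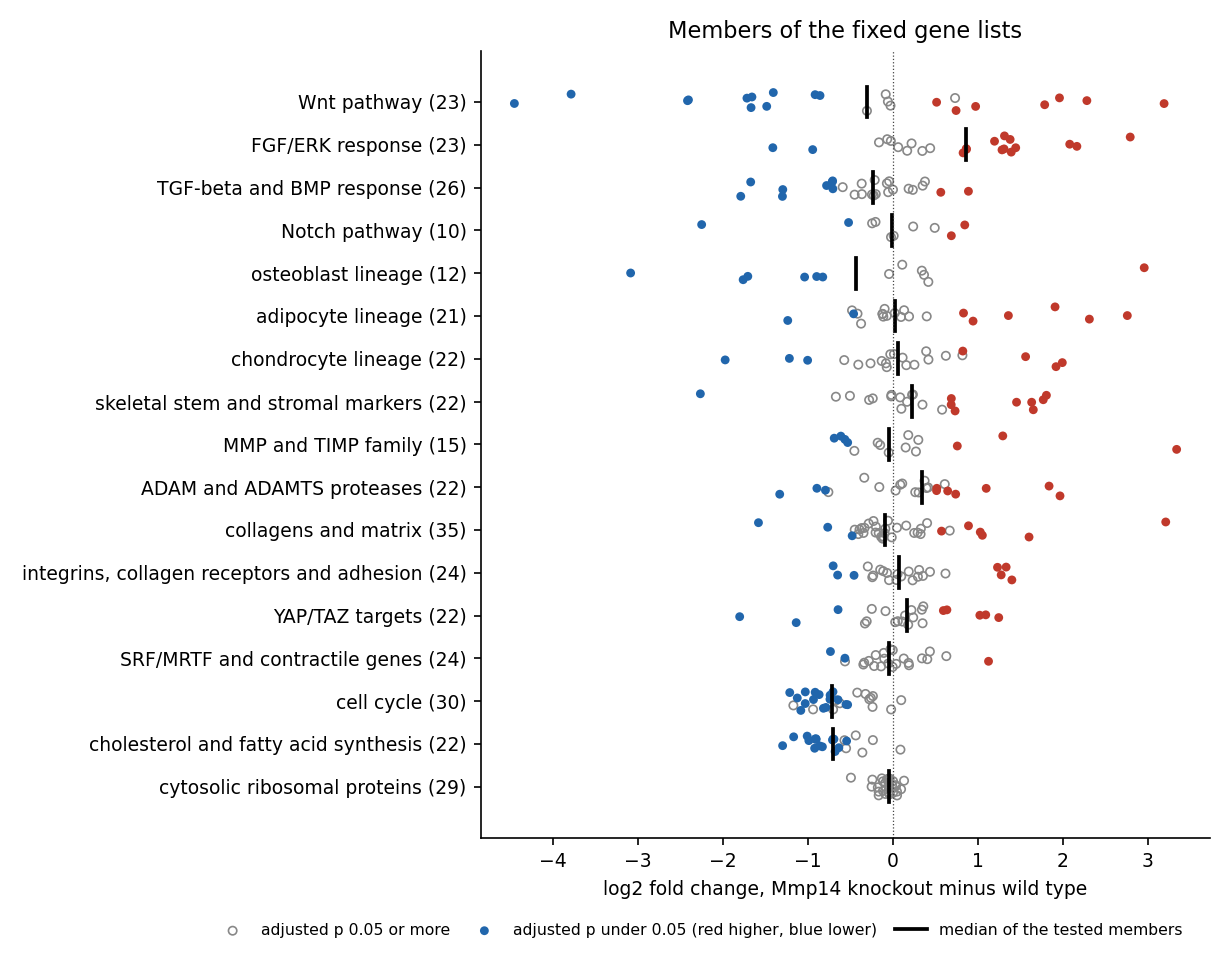
Each point is a tested member of 1 of the fixed gene lists, with its log2 fold change of knockout against wild type on the x axis, filled where called (red higher, blue lower), and black bars are list medians. FGF/ERK response genes lie mostly above 0 (median 0.87), and cell cycle (median −0.71) and cholesterol synthesis genes (median −0.70) mostly below.

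Markers of other cell types were mostly dim. Of 18 macrophage and leukocyte markers, 5 were tested and 0 called by limma over all genes or adjusted over the list alone, with 1 at an unadjusted p below 0.05 (camera adjusted p = 0.344), and Cd68 had a value of −0.12. Of 5 tested osteoclast markers, 1 rose (Mmp9) and 4 were not called, or 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.962). Among pericyte and smooth muscle markers, 1 of 7 fell (Rgs5, −1.07), with the same count adjusted over the list alone (camera adjusted p = 0.896). Of 6 Schwann and neural markers, 1 fell (Ncam1, −0.81), or 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.383). Too few members were bright enough for a list test of granulocyte (1), lymphocyte (2), endothelial (2), erythroid and megakaryocyte (3) and skeletal muscle (3) markers. Of these genes Pax7, from the skeletal muscle list, rose by 1.31 and the others were not called. The muscle factors Myod1, Myf5 and Myog were too dim to be tested. Of the 4 tested Y-linked and X-inactivation genes, 1 rose and 1 fell, or 1 and 2 adjusted over the list alone.

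**Figure D3:**
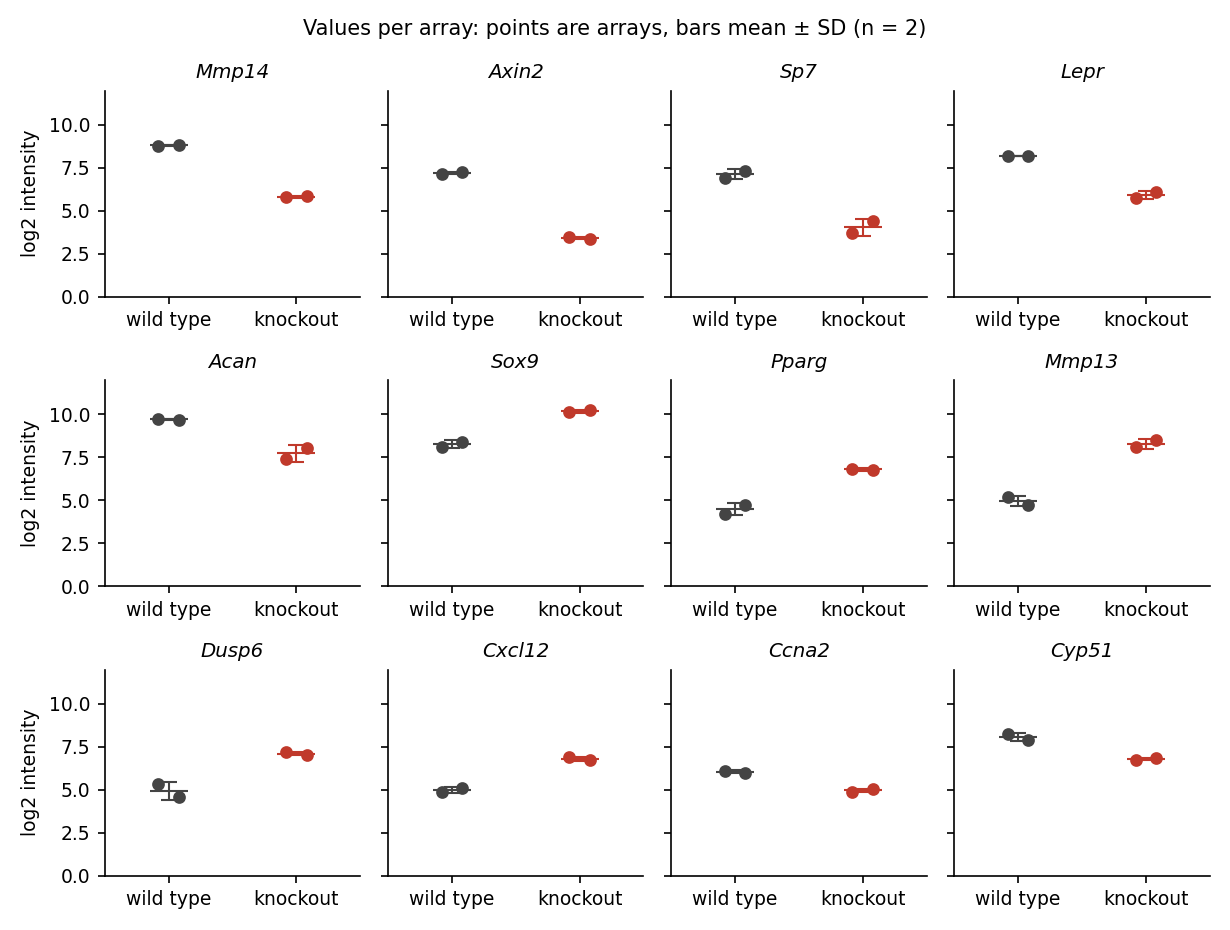
Points are log2 intensities of single arrays for 12 named genes in wild type (grey) and Mmp14 knockout (red), with bars for the mean ± SD (n = 2 per group). Mmp14 lies at 8.77 and 8.83 in wild type and at 5.77 and 5.84 in knockout, and the groups do not overlap in any of the genes shown.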

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

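The calls of Xist and Eif2s3y, and the fits without single arrays, were planned. All other tests in this part were chosen after seeing the data. Of these, only the test of further positional factors had its outcome rule written before its result was seen.

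Signal was also found in probe sets that the comparison of genes did not use. In a fit of all probe sets with a mean of at least 2.34 log2, 13 of 949 probe sets with several listed genes were called (7 higher, 6 lower), as were 60 of 6440 with no listed gene (39 higher, 21 lower). In that fit 195 of 13284 probe sets with 1 gene were higher and 134 lower. The largest change without a listed gene was a rise to 4.97 log2 from a wild-type signal of 1.52. That signal was below the 2.34 set for dim genes, so its fold is not given. The largest change with several listed genes was −1.81.

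Knockout arrays kept 12.6% of the wild-type Mmp14 signal (10.9% to 14.5% with 2 SE). Wild-type cells mixed into the knockout cultures, at their wild-type expression, would leave every gene at least that share. Tnfrsf19 kept 3.63%, and Nkd2 (4.57%) and the unnamed locus C430002N11Rik (6.80%) also lay below the share of Mmp14, which argues against such cells as the whole source. Axin2 lay below it on its brighter probe set only (7.26%), since its fall was 2.55 log2 with the mean of its probe sets. Transcript parts outside the deletion, or other targets of the probes, remain a possible explanation: with 1 Mmp14 probe set no test could separate them. No biological explanation was tested.

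Xist was higher and Eif2s3y lower in knockout, so the sex makeup of the cultures may differ, although Eif2s3y was not called on leaving out any of 3 arrays (adjusted p = 0.0648 to 0.176) nor Xist without Mmp14 knockout replicate 1 (0.0801). The most that such a shift could move a gene was set at 1.01 log2, the larger of the Xist and Y-linked shifts plus 2 SE. This bound assumes a gene used only in cells of 1 sex, and probe sets that report changes alike. Effects of cells of 1 sex on other cells were not bounded. Beyond that bound by a further 2 SE of their own lay 235 called autosomal genes (142 higher, 93 lower), or 17.0% of the 1386. Mmp14, which the genotype removes, was among them. Under these assumptions the rest argue against sex makeup as the whole cause of their changes. For the other 1151 genes, which lay within the bound or beyond it by less than 2 SE of their own, sex makeup and genotype cannot be told apart, because no cultures matched for sex were compared. X-linked genes were called about as often (11.9%) as autosomal genes (11.4%).

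Transcription factors that mark positions in the embryo moved in both directions: Tfap2a (2.75), Pax3 (1.95) and Alx1 (1.81) were higher and Zic2 (−2.39) and Zic1 (−1.94) lower in knockout. Wild-type and knockout cells of different anatomical origin could give such a pattern. Among 32 tested positional factors whose values had not been looked at, 4 were called higher and 3 lower, or 21.9% against 11.3% of all genes (one-sided permutation p = 0.0436 over 10000 draws matched on mean expression, two-sided Fisher exact p = 0.0843), so the result depends on the test chosen. Of 36 Hox genes with a probe set, only 5 passed the filter on dim genes. Limma called 0 of these 5, and 0 had an unadjusted p below 0.05. Their signal lay close to the array medians of 2.32 to 2.37 log2, so a difference between the groups in these 5 genes could hardly be seen. Among all 36, the highest value in any array was 2.80 log2 (Hoxd10 in wild type replicate 1). No Hox gene was thus bright in 1 group and dim in the other. An effect of Mmp14 loss on the positional factors remains as open as a different origin, since origin and genotype were not varied separately.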

How the results depend on the processing

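Each alternative setting was run, and 1 was added after seeing the data: every probe set with trend and robust eBayes. No result reversed. Mmp14 stayed called, at −2.95 to −3.03 log2. The 20 largest changes were called under every gene-level alternative that gave a value, and of the 97 called named genes besides Mmp14, 21 lost the call under at least 1 gene-level alternative (fits of every probe set are not in that count).

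With every probe set of the table, 129 were higher and 89 lower: 41345 rows were tested, with no filter and several probe sets per gene, and the prior had 2.72 degrees of freedom, against 3.99. Dropping the filter on genes alone left 637 and 487. Keeping the filter at 2.34 log2 but taking all bright probe sets left 195 and 134 of 13284 probe sets with 1 gene. That fit also called 7 and 6 of 949 probe sets with several genes and 39 and 21 of 6440 with none. Most of the drop thus came with the filter kept. Taking several probe sets per gene and adding those without exactly 1 gene were not separated. The added fit gave 316 and 231, with 448 of the 1439 genes still called. Trend and robust eBayes on genes gave 1072 and 1027. An adjusted p below 0.1 gave 1240 and 1125, and at least a 2-fold change 272 and 174. Leave-one-out fits assume that a lone array varies like the other group: 672 and 459 without wild type replicate 1, 509 and 448 without wild type replicate 2, 394 and 293 without Mmp14 knockout replicate 1, and 503 and 393 without Mmp14 knockout replicate 2. Fewer arrays were used there, and the cause of the differences between them was not tested. With the stricter filter there were 809 and 835, quantile-normalized 790 and 698, centred 749 and 740, so the balance of higher and lower genes turned under the stricter filter. With the replicate block there were 606 and 451, and 13 of the 97 named genes lost the call. They were Eif2s3y, Itga6, Plk1, Csf1, Car12, Fhl1, Pcolce2, Loxl3, Lox, Notch1, Hes1, Ifit3 and Edem1.

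With an estimated correlation 0 lists were called higher and 0 lower, against 3 and 4, and 0 had an unadjusted p below 0.05, in a test that rests on 2 residual degrees of freedom. Without wild type replicate 1, 1 list was called higher. Fry, which tests a list against no change and not against the other genes, also gave 3 and 4, but not the same lists. Cell cycle, cholesterol and stress response genes reached a fry adjusted p of 0.0692, and ADAM and ADAMTS proteases 0.0705. The Wnt (0.0467), osteoblast (0.0248), p53 (0.0248) and YAP/TAZ (0.0473) lists passed. Signal near the array medians of 2.32 to 2.37 log2 limits what can be said of dim genes.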

Other observations

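All group tests and extra fits in this part, and the choice of genes shown, came after seeing the data. The members of the Wnt and chondrocyte lists were fixed before, and their calls came from the planned comparison. Only the test of further beta-catenin targets had its outcome rule written before its result was seen.

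Other large called changes are given gene by gene, with no test of a group. Hgf (1.92) and Fgf7 (1.64), growth factors for epithelial cells, rose with the prostaglandin receptor gene Ptgfr (2.34), the sphingosine phosphate receptor gene S1pr3 (2.64) and the Wnt receptor gene Fzd4 (2.25). The anion transporter gene Slc26a7 rose by 2.94. Bmp7 (−1.74), Lrrc17 (−2.39), Crispld2 (−2.31) and Klf9 (−1.56) fell. Further transcription factors called were Tfap2b (1.57), Gata2 (1.61), Foxf1 (1.42) and Pax9 (1.35), higher, and Zic4 (−1.56) and Bcl11b (−1.71), lower.

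The fall of Axin2, Nkd2 and Notum could be part of a wider fall of beta-catenin targets. Of 20 targets outside the fixed lists 13 were tested: 2 were called higher and 2 lower, with a median of −0.05 (camera p = 0.692, or 0.716 with an estimated correlation), which leaves the hypothesis open.

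A larger share of chondrocytes in knockout might raise Sox9 (1.92), and Cnmd (1.56), Sox5 (0.83) and Ucma rose with it. Col2a1, at 10.5 log2 the brightest chondrocyte gene of the list in wild type, had a value of −0.0788, and Acan and Comp fell by 1.97 and 1.21. That argues against a larger share as the whole cause, and a change within such cells was not tested.

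Strain DNA kept around Mmp14 could change its neighbours. Of 29 tested genes within 60 annotated genes on either side, 5 were called (17.2% against 11.3% of other genes, two-sided Fisher exact p = 0.37), among them Slc7a7 (−1.44) and Cmtm5 (1.61), which leaves this open.

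Over 132 gene families defined by their symbols, none passed an adjusted p of 0.05, and the smallest was 0.0901 for the Cox genes (21 members, median −0.28). In a fit of all bright probe sets, not the gene-level fit of the report, 14 of 438 genes with several tested probe sets had a call, 13 of them on some probe sets only and 0 in opposite directions.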
